A study of Mus musculus with 19 samples.

How the data were processed

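Total RNA, isolated on silica columns from 7 sorted bone marrow populations, was measured on 19 custom Agilent arrays, 1 per sample. The labels name Cy5 as the dye, and the files hold 1 channel, named green; the values were treated as single-colour. Each array held 62543 spots, 1319 of them controls and the other 61224 of 59628 probes. Per the file headers, the deposited intensity values were made with Agilent Feature Extraction 11.5.1.1 (protocol GE1_1105_Oct12), which subtracts background and flags each spot, and the array annotation used mouse build mm9. The submitters' processing notes name Agilent Feature Extraction with no version. The authors' series values held the background-subtracted intensity of the same spots, without normalization between arrays, and were used as an alternative only.

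The processed signal was taken to log2 and the 75th percentile of each array was subtracted. Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged. A gene with several probes was represented by the probe with the highest mean; the mean of all probes was an alternative. Of 55681 catalogue probes, 27235 were named through a RefSeq list of assembly GRCm38.p6, used for names only, and the others kept the name in the files. This gave 38391 features, of which 20660 were named genes, 4610 intergenic noncoding regions, 11806 other accessions and 1317 custom features with 3947 probes; 2 features with probes of both kinds count as named genes and as other accessions.

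Comparisons were fitted with limma 3.58.1 in R 4.3.3 as cell type means over all 19 arrays, which share 1 estimate of the spread, followed by eBayes and Benjamini-Hochberg adjustment at 0.05. Each of 7 comparisons asked how neighbouring stages or branches of blood formation differ: CMP with LSK, MEP and GMP with CMP, MEP with GMP, early erythroblasts with MEP, late with early erythroblasts, and granulocytes with GMP. An interaction compared the change from MEP to late erythroblasts with that from GMP to granulocytes, and a moderated F test asked which features varied over the 7 cell types. A feature was tested where it was well above background on every array of at least 1 of the groups compared, and called where the higher group was well above background on every array. For the interaction, a feature had to be well above background on every array of all 4 groups, so genes silent in any of them were left out. This filter and this rule for calls were chosen after the floors of the arrays had been seen. A group well above background on none of its arrays has only a bound: the mean of the brighter group was set against the mean, per array, of the higher of the lowest signal well above background and the probe's own signal, and the result is given as at least N-fold. Limma's adjusted p is given with it.

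The 24 gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 168 tests, and again with a correlation estimated from the residuals; 109 tests passed with the first and 10 with the second. The lists held stem and multipotent cell genes, lymphoid genes, erythroid transcription factors, erythroid membrane genes, heme and iron genes, hemoglobin genes, megakaryocyte and platelet genes, primary granule genes, secondary and tertiary granule genes, myeloid transcription factors, cell cycle genes, cell cycle inhibitors, ribosome biogenesis, autophagy and organelle clearance, oxidative phosphorylation, antigen presentation and interferon genes, markers of B cells, T and NK cells, macrophages, monocytes and dendritic cells, eosinophils with basophils and mast cells, and endothelial and stromal cells, known long noncoding RNAs, and sorting markers. Counts of list members are also given adjusted over the list alone. The share of custom features that varied was set against 10000 draws of named genes matched on mean signal in 20 bins, with a two-sided permutation p.

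The groups, comparisons, tests, gene lists, alternatives and the rule for genes named in the text were fixed before the data were examined, apart from those said to be chosen later. Named for each comparison were the 6 largest positive and 6 largest negative differences among genes past the test whose arrays did not overlap and which were well above background on every array of both groups, the 3 largest custom features in each direction by the same rule, and up to 4 members past the test of each relevant list with the largest differences. Also named were Gata1, Gata2, Klf1, Spi1, Cebpa, Cebpe, Gfi1, Gfi1b, Meis1, Hlf, Alas2, Mpo, Ltf, Pf4, Flt3 and the sorting markers Kit, Ly6a, Cd34, Fcgr3, Cd44 and Ly6g, and up to 3 features per cell type among those detected in 1 cell type only. Ddx3y, Xist, the interaction's Ube2o and Egr1, and the further markers in the closing section were chosen after their values were seen. Not every gene that the rule takes is reported here.

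The alternatives chosen beforehand were normexp background correction (offset 50), quantile normalization, the percentile over probes detected on every array, no filter and a stricter filter, the slide as a fixed or random block, the replicate number as a block, the mean of all probes, eBayes with trend and robust options, the values of the authors' series file (floor 10), each array left out, and only the groups compared. The normexp fit used the median foreground signal in place of the mean. A common floor for all arrays, scaling on the E1A spike-in probes, the granulocyte arrays averaged to 1 sample or left out of the fit, a looser filter for the interaction, and counts of 2-fold differences were added after seeing the data. The arrays lay on 5 slides with 1 scan each, and granulocytes and GMP shared no slide.

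The steps were tested on simulated data with 50 features changed per size. For CMP against LSK (24182 features), 10%, 46%, 80% and 96% of log2 changes of 0.5, 1, 2 and 3 were recovered, for MEP against CMP (22842) 12%, 46%, 88% and 92%, for GMP against CMP (22812) 8%, 46%, 84% and 96%, and for the interaction (15099) 0%, 30%, 78% and 96%. Of the 24 lists, only the 1 that had been shifted passed. The simulated features were drawn independently of each other, so this could not show false list calls that arise from correlated genes. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.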

Results

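RNA of 7 blood cell populations from the bone marrow of adult C57BL/6 mice aged 8 to 12 weeks was measured on 19 single-colour arrays, with 1 array per sample. LSK cells, which lack lineage markers and carry Kit and Sca-1, contain the hematopoietic stem cells and multipotent progenitors (3 arrays). Their myeloid descendants were sampled as common myeloid progenitors (CMP, low CD16/32 and high CD34, 3 arrays), megakaryocyte-erythroid progenitors (MEP, low CD16/32 and low CD34, 3 arrays) and granulocyte-macrophage progenitors (GMP, high CD16/32 and high CD34, 2 arrays). The mature stages were Ter119-positive early erythroblasts, large and high in CD44 (2 arrays), Ter119-positive late erythroblasts, small and intermediate in CD44 (3 arrays), and Gr1-positive granulocytes (3 arrays). The array carried probes for 20660 named genes, for 4610 intergenic noncoding regions and for 1317 custom features, which the study had defined by RNA sequencing of blood cells. The custom features formed 4 sets of 155, 60, 378 and 724, and the design text names pseudogenes, genes that overlap small RNAs, and long noncoding RNAs of low and of high stringency. Which set holds which kind is not given in the sources used here, and the sets are numbered 1 to 4.

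The erythroblast arrays were dimmer than all others. The 75th percentile of the signal, in intensity units, lay between 50.1 and 81.3 on the 5 erythroblast arrays and between 266 and 607 on the other 14. Between 42.9% and 47.1% of the spots were well above background on erythroblast arrays, against 49.5% to 66.3% elsewhere. The 100 brightest spots held 28.4% to 39.1% of the signal of an erythroblast array and 12.3% to 15.4% of that of any other. All levels below are relative to the 75th percentile of the array, so they describe composition and not RNA per cell, and the number of arrays limits their precision. Nothing in the labels says whether replicates came from separate animals, and p-values measure only the spread between these samples, which may be technical.

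**Figure D1:**
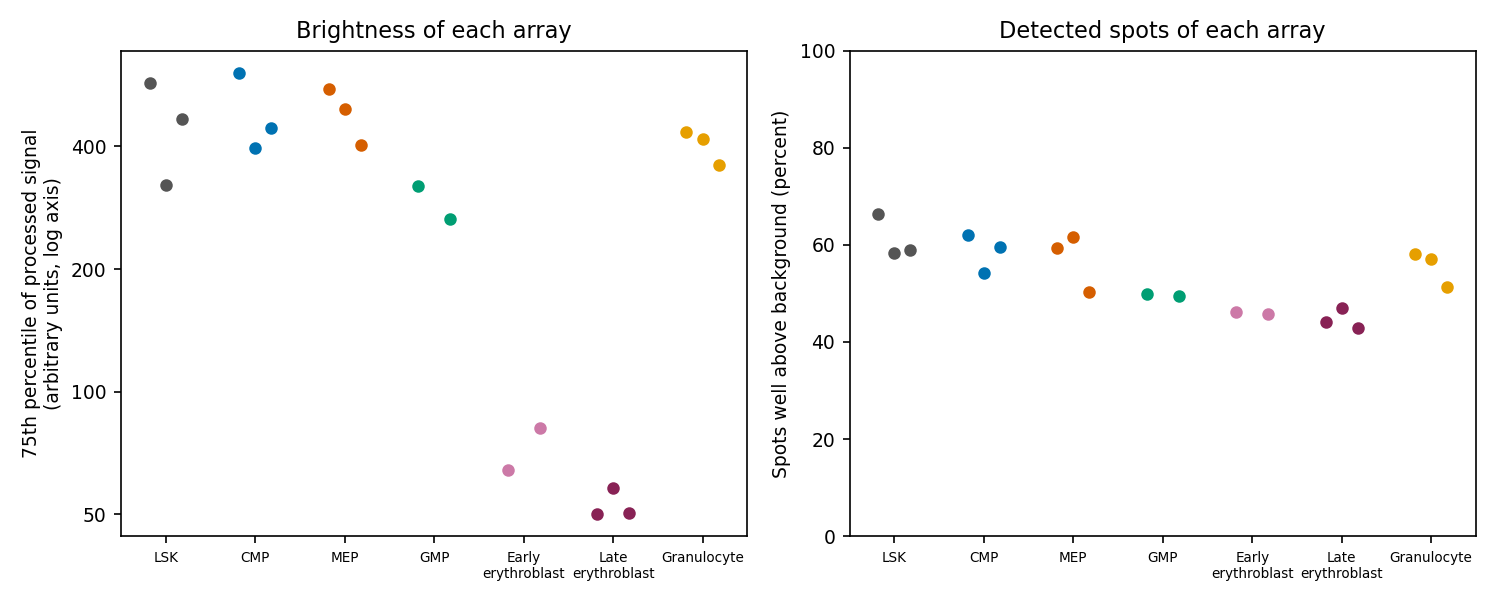
Signal of each of the 19 arrays by cell type, with the 75th percentile of the processed signal on a log axis (intensity units) and the percent of spots well above background, 1 point per array. The 5 erythroblast arrays lie between 50.1 and 81.3 intensity units, under the 266 to 607 of the other arrays.

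Erythroblasts stood apart from the other 5 populations, and CMP and MEP arrays were nearly as alike as replicates. The first principal component held 68.95% of the variance of 14559 features and placed erythroblast arrays between 167.85 and 203.88 and all others between -93.31 and -36.07. Across features, which are not independent replicates, arrays of 1 cell type correlated with r between 0.985 and 0.998, CMP with MEP arrays between 0.983 and 0.996, and MEP with early erythroblast arrays between 0.716 and 0.752. Lineage genes marked the populations. Hlf, a transcription factor of stem cells, had its highest mean level in LSK cells (4.53 log2 units above the 75th percentile). Gata1, the erythroid and megakaryocytic regulator, reached 7.87 in early erythroblasts, Cebpe, a regulator of granulocyte maturation, reached 8.18 in granulocytes, and Pf4, platelet factor 4, stood at 6.09 in CMP and 5.97 in MEP.

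**Figure D2:**
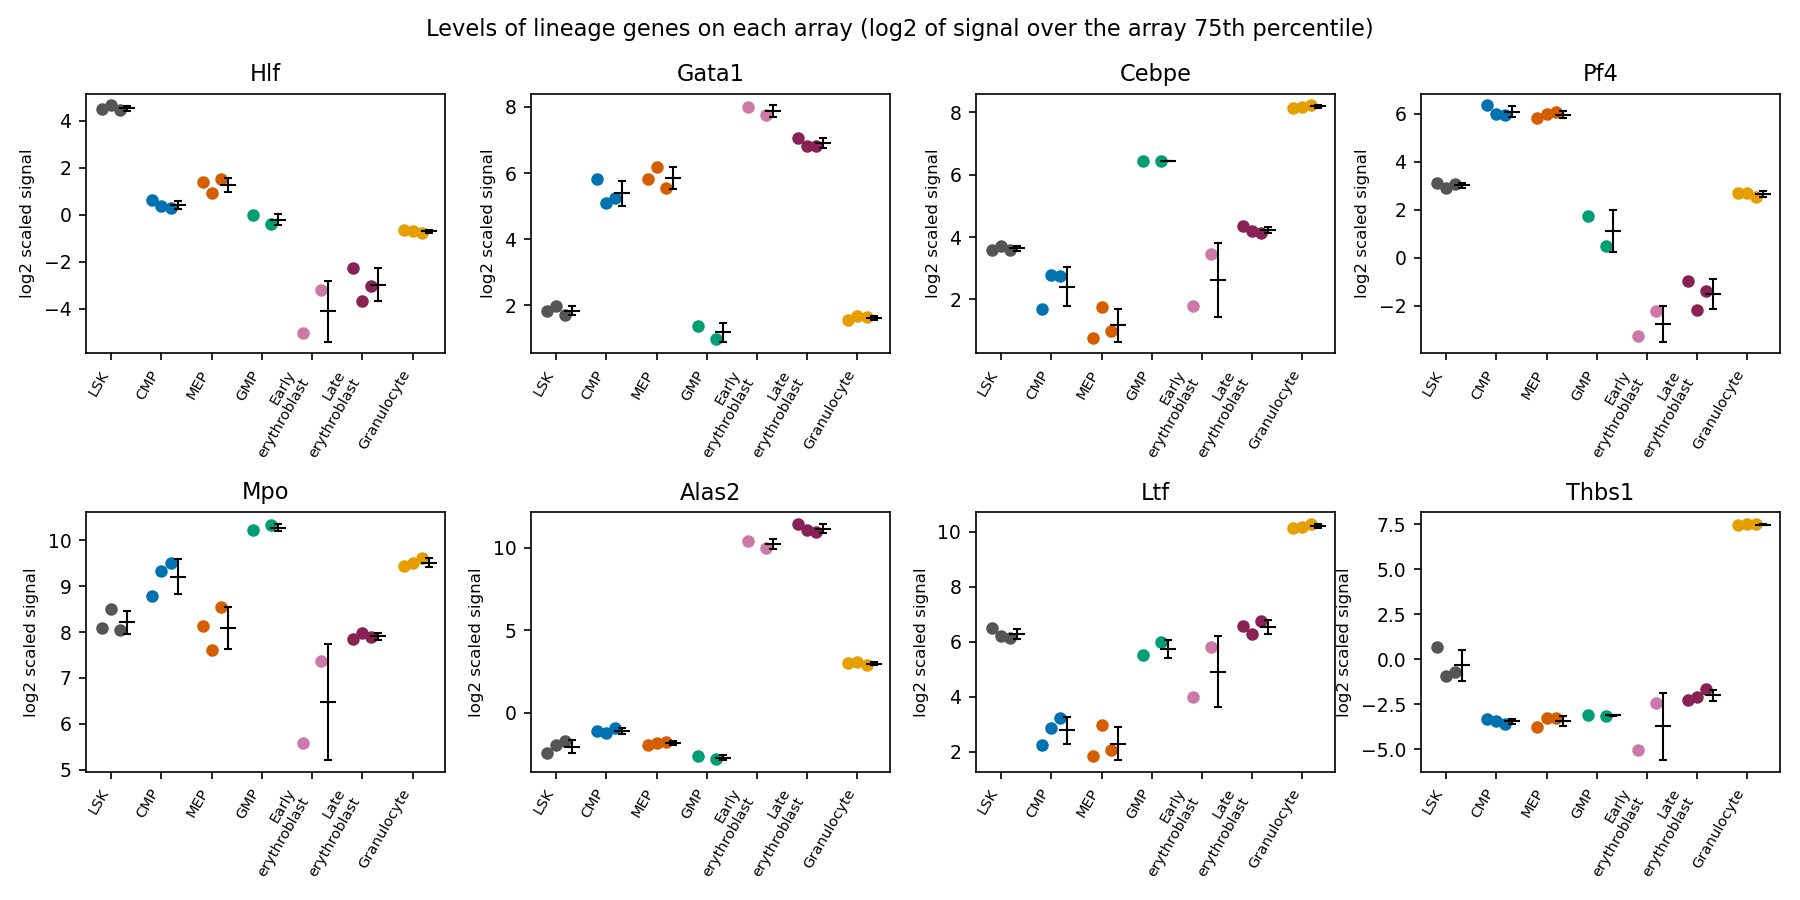
Levels of 8 lineage genes per array (log2 signal relative to the 75th percentile of the array), 1 point per array with the mean and SD of each cell type. Hlf has its highest mean in LSK cells (4.53), Gata1 in early erythroblasts (7.87) and Cebpe in granulocytes (8.18), and Pf4 has similar means in CMP (6.09) and MEP (5.97).

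From LSK to CMP, stem cell genes fell, and erythroid membrane and heme genes and genes of growth and division rose. Procr, the endothelial protein C receptor of stem cells, fell by 4.68 ± 0.26 (log2 difference ± SE, 3 against 3 arrays), and Mn1, a transcriptional regulator of progenitors, fell by 3.68 ± 0.30. Klf1, an erythroid transcription factor, rose by 4.35 ± 0.27, the erythropoietin receptor gene Epor by 4.23 ± 0.21 and Gata1 by 3.55 ± 0.20. Pf4 rose by 3.07 ± 0.34, and the monocytic genes Irf8, a transcription factor, and Csf1r, the receptor for colony stimulating factor 1, rose by 2.71 ± 0.22 and 2.13 ± 0.26. These 8 genes had limma adjusted p-values of at most 1.9e-05.

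Of 30 stem cell genes tested, 23 were lower in CMP and 0 higher (25 lower adjusted over the list alone), with camera adjusted p = 3.42e-13 and adjusted p = 0.00563 with an estimated correlation. Of 15 lymphoid and early multipotent genes, 9 were lower (9 adjusted over the list alone; camera adjusted p = 2.3e-06, and adjusted p = 0.0302 with an estimated correlation). Among them, lymphotoxin beta (Ltb) fell by 4.83 ± 0.32 and the chemokine receptor gene Ccr9 by 4.72 ± 0.26, while the recombinase gene Rag1 was well above background on 0 of 3 CMP arrays and at least 9.1-fold lower there (adjusted p = 7.5e-07). Of 25 erythroid membrane genes, 24 were higher and 1 lower (24 and 1 adjusted over the list alone), with camera adjusted p = 9.71e-14 and adjusted p = 0.156 with an estimated correlation. Sphk1, a sphingosine kinase, rose by 4.99 ± 0.24, Ermap by 4.87 ± 0.26 and the blood group gene Kel by 4.73 ± 0.21. Heme and iron genes were higher for 18 of 24 (20 adjusted over the list alone), with camera adjusted p = 6.07e-08 and adjusted p = 0.169 with an estimated correlation. Cpox, a heme synthesis enzyme, rose by 2.67 ± 0.18. Erythroid transcription factors were higher for 7 of 17 and lower for 4 (7 and 5 adjusted over the list alone; camera adjusted p = 0.437). Platelet and megakaryocyte genes were higher for 12 of 26 and lower for 6 (14 and 6 adjusted over the list alone; camera adjusted p = 0.492), and monocyte and dendritic cell markers for 7 of 15 and 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0698).

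Of 44 cell cycle genes, 40 were higher in CMP (41 adjusted over the list alone), among them cyclin E1 (Ccne1, 2.97 ± 0.15), with camera adjusted p = 2.39e-12 and adjusted p = 0.154 with an estimated correlation. Cell cycle inhibitors were lower for 7 of 13 and higher for 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00812, and adjusted p = 0.226 with an estimated correlation), and Cdkn1c, which encodes p57, fell by 3.02 ± 0.32. Ribosome biogenesis genes were higher for 31 of 35 (33 adjusted over the list alone) and oxidative phosphorylation genes for 34 of 36 (36 adjusted over the list alone). Their camera adjusted p-values were 3.75e-08 and 5.76e-12, and the values were adjusted p = 0.169 and adjusted p = 0.119 with an estimated correlation. Of 27 antigen presentation and interferon genes, 16 were lower in CMP (16 adjusted over the list alone; camera adjusted p = 2.57e-09, and adjusted p = 0.0302 with an estimated correlation), such as Oasl2, which fell by 3.04 ± 0.15.

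Genes known from mature neutrophils and lymphocytes were also higher on LSK than on CMP arrays. Of 39 neutrophil granule and receptor genes of the secondary and tertiary type, 32 were lower in CMP and 2 higher (32 and 2 adjusted over the list alone), with camera adjusted p = 2.78e-14 and adjusted p = 0.158 with an estimated correlation. The gelatinase gene Mmp9 fell by 4.51 ± 0.48, Retnlg by 4.42 ± 0.30 and lactotransferrin (Ltf) by 3.49 ± 0.39. T and NK cell markers were lower for 12 of 16 (13 adjusted over the list alone; camera adjusted p = 1.24e-06, and adjusted p = 0.156 with an estimated correlation). Lck, a T cell kinase, fell by 2.96 ± 0.12. B cell markers were lower for 7 of 15 (7 adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.169 with an estimated correlation). In all, 8893 of 24182 features differed, 5638 higher and 3255 lower in CMP, and of those that differed by 2-fold or more 1445 were higher and 2141 lower. With the slide as a block 8750 were called, and on the slides that held both cell types, 3 and 4, 99.96% and 99.93% of the calls had the same sign. The calls were made from these same arrays, so such shares are high by construction. Here and in the comparisons below they are no separate evidence on the slides. The share of calls that were higher was 63.4% here, 51.4% with quantile normalization, 32.3% with the percentile taken over probes detected on every array and 45.7% of only 1747 calls with spike-in scaling, and the median of all features moved from 0.17 to 0.09, -0.15 and 0.51.

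MEP and CMP differed in 1032 features, among them lower myeloid and cell division genes and higher stem cell genes in MEP (3 against 3 arrays). F13a1, coagulation factor XIII of monocytes and platelets, fell by 3.09 ± 0.27 (adjusted p = 3.0e-04), the protease inhibitor gene Slpi by 2.45 ± 0.32, Csf1r by 2.03 ± 0.26 and Irf8 by 1.63 ± 0.22. Neutrophil elastase (Elane) fell by 2.02 ± 0.33. Gata2, a regulator of stem and progenitor cells, rose by 1.40 ± 0.19 (adjusted p = 1.4e-03), and Slamf1, a surface receptor of stem cells, rose by 1.80 ± 0.26. Gata1 at 0.46 ± 0.19 (adjusted p = 0.24) and Klf1 at 0.38 ± 0.27 (adjusted p = 0.55) did not pass the test. Of 16 erythroid transcription factors, 2 were higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.000288, and adjusted p = 0.277 with an estimated correlation). Cd34, whose protein separates these populations in the sort, was at -0.52 ± 0.31 (adjusted p = 0.45).

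Of 44 cell cycle genes, 22 were lower in MEP and 0 higher (34 lower adjusted over the list alone), with camera adjusted p = 1.29e-20 and adjusted p = 0.0655 with an estimated correlation. The mitotic genes Nusap1 and Kif20a fell by 0.95 ± 0.16 and 0.86 ± 0.14. Of 28 stem cell genes, 6 were higher (7 adjusted over the list alone; camera adjusted p = 8.59e-08, and adjusted p = 0.021 with an estimated correlation). Platelet and megakaryocyte genes were higher for 3 of 26 (8 adjusted over the list alone), with camera adjusted p = 1.64e-05 and adjusted p = 0.158 with an estimated correlation. Of 22 myeloid transcription factors and receptors, 6 were lower (11 adjusted over the list alone; camera adjusted p = 1.73e-06, and adjusted p = 0.217 with an estimated correlation). So were 5 of 15 primary granule genes (9 adjusted over the list alone; camera adjusted p = 9.05e-06, and adjusted p = 0.254 with an estimated correlation). Of 15 monocyte and dendritic cell markers, 6 were lower (8 adjusted over the list alone; camera adjusted p = 5.43e-05, and adjusted p = 0.156 with an estimated correlation).

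Hemoglobin genes were lower in MEP than in CMP for 4 of 6 tested (5 adjusted over the list alone; camera adjusted p = 0.000642, and adjusted p = 0.159 with an estimated correlation), with Hbb-bt down by a log2 difference of -0.92 ± 0.17. T and NK cell markers were higher for 5 of 15 (11 adjusted over the list alone; camera adjusted p = 1.16e-07, and adjusted p = 0.119 with an estimated correlation). Antigen presentation and interferon genes were higher for 4 of 26 (8 adjusted over the list alone; camera adjusted p = 8.08e-08, and adjusted p = 0.0589 with an estimated correlation). The noncoding RNA Malat1 rose by 1.22 ± 0.14. In all, 1032 of 22842 features differed, 426 higher and 606 lower, or 41.3% higher, against 62.9% with the percentile over detected probes and 29.2% of only 24 calls with spike-in scaling. With the slide as a block 1142 were called, the sign was shared on slides 2, 3 and 4 by 99.81%, 100% and 100% of the calls, and without 1 array the count was 302 (CMP 2), 325 (CMP 3), 525 (MEP 2) or 492 (MEP 3). The CMP arrays were not all alike. On the fourth principal component (2.93% of the variance) CMP 1 lay at 8.44 and CMP 2 and CMP 3 at -8.34 and -9.19. MEP arrays lay between 15.44 and 20.3. On the third CMP 1 (10.26) lay with CMP 2 and CMP 3 (11.94 and 10.11). Myeloid transcription factors and receptors had a median of 1.85 on CMP 1, against 2.78 and 2.76 on CMP 2 and CMP 3. On MEP arrays it was 1.499 to 1.915. The bearing of CMP 1 on the count stays open. The calls rest on the spread estimated over all 19 arrays. Fitted on these 6 arrays alone, without the slide as a block, limma called 0 features after adjustment. At an unadjusted p under 0.05 that fit had 4268 of 22842.

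GMP were set apart from CMP by granule genes on one side and by the loss of erythroid and platelet genes on the other (2 against 3 arrays). Cebpe rose by 4.03 ± 0.41, the transcriptional repressor gene Gfi1 by 3.06 ± 0.26 and Elane by 3.27 ± 0.37. The eosinophil granule genes Prg2 and Prg3 rose by 4.46 ± 0.39 and 4.50 ± 0.35, and eosinophil peroxidase (Epx) by 4.39 ± 0.70. Epor fell by 5.47 ± 0.24, Klf1 by 5.13 ± 0.30 and Pf4 by 4.99 ± 0.37. Of these genes, Epx had the highest adjusted p (3.3e-04).

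Primary granule genes were higher in GMP for 14 of 15 (15 adjusted over the list alone), with camera adjusted p = 1.46e-09 and adjusted p = 0.163 with an estimated correlation. Secondary and tertiary granule genes were higher for 30 of 38 and lower for 1 (31 and 2 adjusted over the list alone), with camera adjusted p = 3.42e-13 and adjusted p = 0.162 with an estimated correlation. The neutrophil surface gene Cd177 rose by 3.42 ± 0.40 and Ltf by 2.96 ± 0.44. Eosinophil, basophil and mast cell markers were higher for 12 of 18 and lower for 1 (13 and 1 adjusted over the list alone; camera adjusted p = 8.59e-08, and adjusted p = 0.108 with an estimated correlation). Of 25 erythroid membrane genes, 22 were lower (22 adjusted over the list alone; camera adjusted p = 3.6e-30, and adjusted p = 0.0535 with an estimated correlation). The adducin gene Add2 fell by 5.95 ± 0.27. Rhag, of the Rh blood group complex, was well above background on 0 of 2 GMP arrays and at least 34.8-fold lower (adjusted p = 7.0e-09). Of 26 platelet and megakaryocyte genes, 19 were lower and 1 higher (21 and 1 adjusted over the list alone), with camera adjusted p = 1.17e-14 and adjusted p = 0.0302 with an estimated correlation. Stem cell genes were lower for 18 of 28 and higher for 0 (19 and 1 adjusted over the list alone; camera adjusted p = 1.18e-10, and adjusted p = 0.00563 with an estimated correlation). The lymphoid genes Dntt, a DNA polymerase of lymphocyte precursors, and Flt3, a growth factor receptor, fell by 5.01 ± 0.36 and 3.82 ± 0.34.

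Cell cycle genes differed for 4 of 44, 3 higher and 1 lower (1 and 1 adjusted over the list alone), with a median of 0.08 that turned to -0.001, -0.07 and -0.64 with quantile normalization, the percentile over detected probes and spike-in scaling. Of 35 ribosome biogenesis genes, limma called 0 (0 adjusted over the list alone). In all, 4109 of 22812 features differed, 2174 higher and 1935 lower. The share higher was 52.9%, against 42.4% with quantile normalization, 36.0% with the percentile over detected probes, 63.2% after normexp background correction and 15.4% of 1677 calls with spike-in scaling, where the median of all features was -0.68. With the slide as a block 3397 were called, and on slide 3 99.98% of the calls had the same sign.

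Of the branches of the myeloid tree, MEP had higher erythroid, platelet and stem cell genes and GMP higher granule genes (3 against 2 arrays). Epor was higher in MEP by 5.68 ± 0.24, Klf1 by 5.51 ± 0.30, Gata1 by 4.67 ± 0.22, Gata2 by 3.30 ± 0.21 and F2r by 5.72 ± 0.28. Elane was lower in MEP by a log2 difference of -5.29 ± 0.37, the myeloid membrane gene Ms4a3 by -5.50 ± 0.39, Cebpe by -5.26 ± 0.41 and Prom1, a membrane glycoprotein, by -6.18 ± 0.48. All 9 had adjusted p-values of at most 1.8e-07.

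Erythroid membrane genes were higher in MEP for 21 of 25 (22 adjusted over the list alone; camera adjusted p = 4.49e-21, and adjusted p = 0.0841 with an estimated correlation). Platelet and megakaryocyte genes were higher for 18 of 25 and lower for 1 (18 and 1 adjusted over the list alone), and stem cell genes for 22 of 28 (22 adjusted over the list alone). Their camera adjusted p-values were 4.66e-13 and 1.67e-11, with adjusted p = 0.0302 and adjusted p = 0.00563 with an estimated correlation. All 15 primary granule genes were lower in MEP (15 adjusted over the list alone; camera adjusted p = 3.03e-09, and adjusted p = 0.169 with an estimated correlation). Of 38 secondary and tertiary granule genes, 31 were lower and 2 higher (32 and 2 adjusted over the list alone; camera adjusted p = 1.21e-10, and adjusted p = 0.192 with an estimated correlation). Cell cycle genes were lower in MEP for 28 of 43 and higher for 1 (31 and 1 adjusted over the list alone), with camera adjusted p = 6.14e-07 and adjusted p = 0.231 with an estimated correlation, and their median of -0.82 moved to -0.07 with spike-in scaling. Antigen presentation and interferon genes were higher for 15 of 26 and lower for 1 (16 and 2 adjusted over the list alone; camera adjusted p = 7.36e-06, and adjusted p = 0.105 with an estimated correlation), such as Cd74, the invariant chain of class II molecules (3.56 ± 0.38).

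Between MEP and GMP 7026 of 21938 features differed, 2973 higher and 4053 lower in MEP. The share higher was 42.3%, against 54.2% with quantile normalization, 66.1% with the percentile over detected probes and 81.7% of 2966 calls with spike-in scaling, where the median of all features moved from -0.07 to 0.68. With the slide as a block 6339 were called, and on slide 3 100% of the calls had the same sign.

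**Figure D3:**
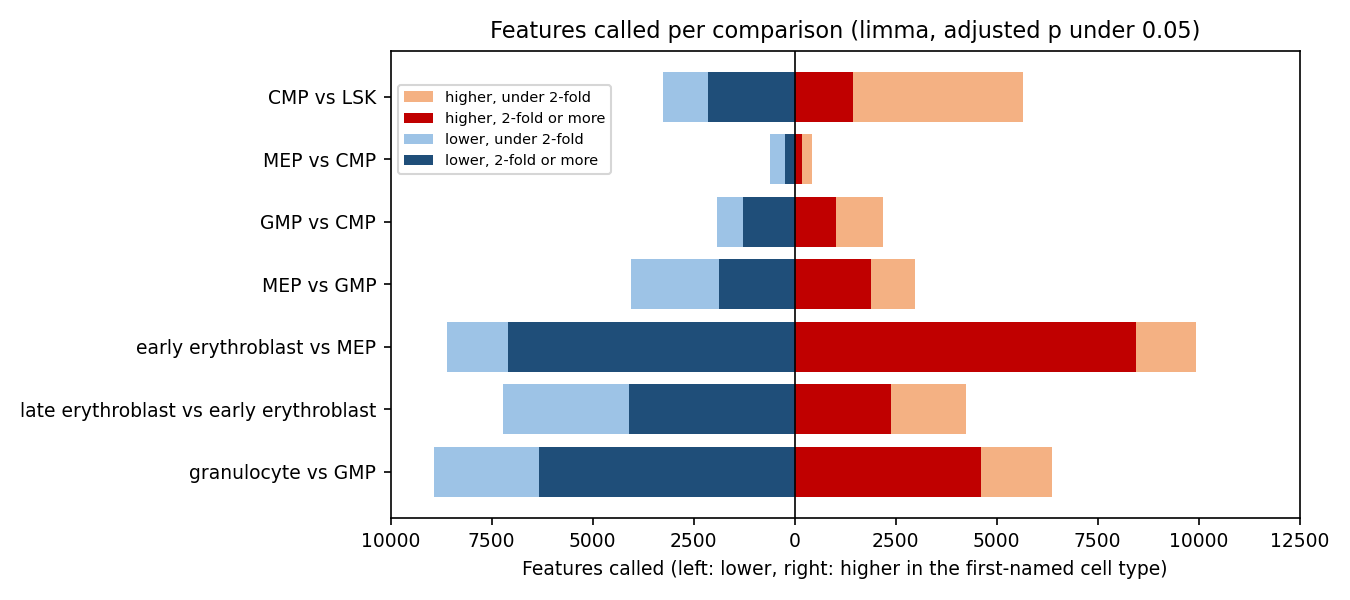
Number of features called higher and lower in each of the 7 comparisons, over all calls and over those of 2-fold or more. MEP and CMP differ in 1032 features and early erythroblasts and MEP in 18552, of which 9943 are higher, a split that turns to 3.2% higher with spike-in scaling.

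From MEP to early erythroblasts hemoglobin, heme and erythroid membrane genes rose, and ribosome biogenesis genes fell (2 against 3 arrays). The anion exchanger gene Slc4a1 rose by 12.46 ± 0.24, Alas2, the first enzyme of erythroid heme synthesis, by 12.05 ± 0.21, and the beta globin gene Hbb-bs by 11.40 ± 0.27. The theta globin gene Hbq1b was well above background on 0 of 3 MEP arrays and at least 961-fold higher in early erythroblasts (adjusted p = 2.6e-13). Gata2 was well above background on 0 of 2 early erythroblast arrays and at least 198.6-fold lower there (adjusted p = 3.0e-13), Meis1, a stem cell homeobox gene, at least 137.2-fold lower (adjusted p = 3.2e-12) and Flt3 at least 103.6-fold lower (adjusted p = 3.1e-11). Pf4 fell by 8.71 ± 0.37 and Myc, the growth regulator, by 6.14 ± 0.54, each well above background on only 1 of 2 early erythroblast arrays.

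All 9 hemoglobin genes tested were higher (9 adjusted over the list alone), with a median of 9.24, camera adjusted p = 6.12e-06 and adjusted p = 0.0431 with an estimated correlation. Heme and iron genes were higher for 23 of 24 (23 adjusted over the list alone; camera adjusted p = 1.13e-10, and adjusted p = 0.143 with an estimated correlation), among them Slc25a37, the mitochondrial iron importer (7.07 ± 0.19). Erythroid membrane genes were higher for 25 of 27 and lower for 2 (25 and 2 adjusted over the list alone; camera adjusted p = 1.67e-09, and adjusted p = 0.181 with an estimated correlation). With spike-in scaling the median moved from 4.09 to 0.60 for heme and iron genes and from 5.45 to 1.95 for erythroid membrane genes. Erythroid transcription factors were higher for 13 of 17 and lower for 4 (13 and 4 adjusted over the list alone; camera adjusted p = 0.00276, and adjusted p = 0.378 with an estimated correlation), and their median turned from 2.02 to -1.48 with spike-in scaling. E2f2, a cell cycle regulator, rose by 7.05 ± 0.17. Gata1 and Klf1 rose by 2.02 ± 0.22 and 2.96 ± 0.30, and both turned negative under spike-in scaling.

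Cell cycle genes were higher in early erythroblasts for 38 of 44 and lower for 3 (38 and 3 adjusted over the list alone), with camera adjusted p = 9.01e-10 and adjusted p = 0.165 with an estimated correlation, and their median of 3.11 turned to -0.38 under spike-in scaling. The proliferation marker Mki67 rose by 5.19 ± 0.13. Inhibitors of division were higher for 8 of 14 and lower for 4 (8 and 4 adjusted over the list alone), with camera adjusted p = 0.0282 and adjusted p = 0.257 with an estimated correlation, and their median of 2.59 turned to -0.91 under spike-in scaling. Among them, Cdkn2d rose by 5.24 ± 0.17. Autophagy and organelle clearance genes were higher for 21 of 27 and lower for 4 (21 and 4 adjusted over the list alone), with camera adjusted p = 8.68e-05 and adjusted p = 0.253 with an estimated correlation, and their median of 2.05 turned to -1.44 under spike-in scaling. Ribosome biogenesis genes were lower for 34 of 35 (34 adjusted over the list alone), with a median of -3.97, camera adjusted p = 1.35e-09 and adjusted p = 0.158 with an estimated correlation. Stem cell genes were lower for 24 of 28 and higher for 3 (24 and 3 adjusted over the list alone), with camera adjusted p = 0.000257 and adjusted p = 0.0655 with an estimated correlation. Platelet genes were lower for 19 of 26 and higher for 2 (19 and 2 adjusted over the list alone), with camera adjusted p = 0.00265 and adjusted p = 0.226 with an estimated correlation. Of 26 antigen presentation and interferon genes, 9 were higher and 16 lower (9 and 16 adjusted over the list alone; camera adjusted p = 0.64). The interferon genes Rsad2 and Isg15 rose by 7.74 ± 0.15 and 5.77 ± 0.17, and the class II gene H2-Ab1 fell by 4.83 ± 0.28.

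Macrophage markers were higher in early erythroblasts than in MEP for 11 of 15 and lower for 2 (11 and 2 adjusted over the list alone), with a median of 2.13 that turned to -1.36 under spike-in scaling. Their camera adjusted p was 0.0122, and adjusted p = 0.345 with an estimated correlation. C1qc, a complement gene of macrophages, rose by 3.89 ± 0.41 and was well above background on 2 of 3 MEP arrays. Secondary and tertiary granule genes of neutrophils were higher for 22 of 35 and lower for 6 (22 and 6 adjusted over the list alone), with camera adjusted p = 0.0147 and adjusted p = 0.587 with an estimated correlation, and their median of 2.10 turned to -1.40 under spike-in scaling. Primary granule genes were lower for 10 of 14 (10 adjusted over the list alone; camera adjusted p = 0.0734), and monocyte and dendritic cell markers lower for 11 of 15 and higher for 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0759). The median level of the primary granule genes was 1.48 and 3.30 on early erythroblast replicates 1 and 2, against 3.54 to 4.02 on MEP arrays. In all, 18552 of 22791 features differed, 9943 higher and 8609 lower, and the count was 18463 with the slide as a block, with 99.89% of the signs shared on slide 3. The share higher was 53.6%, and with spike-in scaling, which moved every log2 difference by -3.50, it was 3.2%; the median of all features was 0.23 here and -0.02 with quantile normalization, and among features under -4 in MEP 1255 of 1304 were called higher.

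From early to late erythroblasts, division and respiration genes fell while genes of autophagy and organelle clearance rose (3 against 2 arrays). The mitotic genes Top2a, Cdc20 and Aurka fell by 2.06 ± 0.25, 2.05 ± 0.16 and 2.03 ± 0.13, and Cyc1, of respiratory complex III, by 1.37 ± 0.19. Xpo7, a nuclear export receptor of late erythroid cells, rose by 4.27 ± 0.20, the ubiquitin-conjugating enzyme gene Ube2h by 3.27 ± 0.23 and Trim58, a ubiquitin ligase of enucleating cells, by 2.67 ± 0.41. Cdkn1b, which encodes the cell cycle inhibitor p27, rose by 1.74 ± 0.11, and Oasl2 by 3.45 ± 0.17. All 9 had adjusted p-values of at most 6.2e-05. Gata1 fell by 0.97 ± 0.21 and Klf1 by 1.14 ± 0.30, the latter not called without early erythroblast replicate 1.

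Of 44 cell cycle genes, 41 were lower in late erythroblasts (41 adjusted over the list alone; camera adjusted p = 3.03e-09, and adjusted p = 0.169 with an estimated correlation). Of 36 oxidative phosphorylation genes, 35 were lower and 0 higher (35 and 1 adjusted over the list alone; camera adjusted p = 1.02e-05, and adjusted p = 0.229 with an estimated correlation). Autophagy and clearance genes were higher for 17 of 28 and lower for 4 (17 and 4 adjusted over the list alone; camera adjusted p = 1.25e-07, and adjusted p = 0.163 with an estimated correlation), and their median of 1.15 moved to 0.22 with spike-in scaling. Hemoglobin genes were higher for 6 of 10 (8 adjusted over the list alone; camera adjusted p = 0.00233, and adjusted p = 0.0841 with an estimated correlation), and their median of 0.64 turned to -0.29 under spike-in scaling. The 6 included the embryonic globin genes Hbb-y (1.48 ± 0.32) and Hbb-bh1 (1.57 ± 0.45). Antigen presentation and interferon genes were higher for 16 of 26 and lower for 4 (16 and 4 adjusted over the list alone), with camera adjusted p = 0.000185 and adjusted p = 0.156 with an estimated correlation, and their median of 0.69 turned to -0.25 under spike-in scaling. Heme genes split, with 6 of 24 higher and 9 lower (6 and 9 adjusted over the list alone); their median was -0.19 although camera put the list upward (adjusted p = 0.723), and the median turned to 0.06 with quantile normalization and 0.18 with the percentile over detected probes.

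Granule genes of neutrophils were higher on late than on early erythroblast arrays, for 34 of 38 of the secondary and tertiary type (35 adjusted over the list alone; camera adjusted p = 6.97e-10, and adjusted p = 0.204 with an estimated correlation). So were 12 of 14 of the primary type (13 adjusted over the list alone; camera adjusted p = 0.000132, and adjusted p = 0.308 with an estimated correlation). With spike-in scaling the medians moved from 1.49 to 0.56 and from 1.26 to 0.33. The 2 early erythroblast arrays differed in level. The median of the primary type was 1.48 on replicate 1 and 3.30 on replicate 2, against 3.56 to 3.70 on late arrays. That of the secondary and tertiary type was -0.22 and 0.83, against 1.92 to 1.97. The rise of the primary type thus rests largely on replicate 1. The collagenase gene Mmp8 rose by 2.21 ± 0.33, Ltf by 1.63 ± 0.43 and myeloperoxidase (Mpo) by 1.43 ± 0.39, and neither of the last pair was called without early erythroblast replicate 1. Myeloid transcription factors and receptors were higher for 17 of 22 (17 adjusted over the list alone; camera adjusted p = 4.66e-05, and adjusted p = 0.253 with an estimated correlation). Monocyte and dendritic cell markers were higher for 9 of 12 and lower for 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00108, and adjusted p = 0.169 with an estimated correlation). In all, 11455 of 19138 features differed, 4237 higher and 7218 lower, and with the slide as a block 12281, with 99.69% of the signs shared on slide 1 and 99.74% on slide 3. The share higher was 37.0%, against 55.6% with the percentile over detected probes and 2.7% with spike-in scaling, where the medians of all features were -0.17, 0.21 and -1.10.

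Granulocytes differed from GMP by mature neutrophil genes, a loss of growth genes, and genes of other blood lineages (3 against 2 arrays). The interleukin 1 decoy receptor gene Il1r2 rose by 8.52 ± 0.68, the formyl peptide receptor gene Fpr1 by 7.36 ± 0.41, Adam8, a protease, by 7.46 ± 0.25, and Ltf by 4.46 ± 0.44. Thrombospondin 1 (Thbs1), a platelet and matrix protein gene, rose by 10.60 ± 0.56. Myc fell by 3.23 ± 0.54, Gins2, of the replication machinery, by 2.18 ± 0.19 and Hoxa7, a homeobox gene of progenitors, by 3.61 ± 0.13. All 8 had adjusted p-values of at most 8.7e-05.

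Secondary and tertiary granule genes were higher in granulocytes for 36 of 39 (36 adjusted over the list alone), with a median of 4.66, camera adjusted p = 1.09e-16 and adjusted p = 0.143 with an estimated correlation. Primary granule genes were lower for 11 of 15 (11 adjusted over the list alone; camera adjusted p = 0.0662), and Mpo was at -0.76 ± 0.39 (adjusted p = 0.098). Ribosome biogenesis genes were lower for 34 of 35 (34 adjusted over the list alone; camera adjusted p = 1.95e-09, and adjusted p = 0.159 with an estimated correlation). All 36 oxidative phosphorylation genes were lower (36 adjusted over the list alone; camera adjusted p = 2.11e-07, and adjusted p = 0.177 with an estimated correlation). Cell cycle genes were lower for 25 of 44 (25 adjusted over the list alone; camera adjusted p = 0.00338, and adjusted p = 0.444 with an estimated correlation), and their median of -0.51 moved to -0.16 with spike-in scaling. Inhibitors of division were higher for 12 of 15 (13 adjusted over the list alone; camera adjusted p = 4.78e-07, and adjusted p = 0.0589 with an estimated correlation), such as Mxd1, an antagonist of Myc (5.47 ± 0.14). Autophagy genes were higher for 15 of 26 and lower for 5 (15 and 5 adjusted over the list alone; camera adjusted p = 0.000594, and adjusted p = 0.292 with an estimated correlation).

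The granulocyte arrays carried markers of B cells, T cells, macrophages and red cells beside these gene groups. B cell markers were higher for 12 of 15 (12 adjusted over the list alone; camera adjusted p = 1.98e-06, and adjusted p = 0.0655 with an estimated correlation). Pou2af1, a transcriptional coactivator of B cells, was at least 131-fold higher (adjusted p = 4.88e-09). T and NK cell markers were higher for 16 of 17 (16 adjusted over the list alone; camera adjusted p = 8.59e-08, and adjusted p = 0.122 with an estimated correlation). Cd3d rose by 5.37 ± 0.35. Macrophage markers were higher for 15 of 16 (15 adjusted over the list alone; camera adjusted p = 5.04e-10, and adjusted p = 0.0589 with an estimated correlation). The complement gene C1qa, well above background on 1 of 2 GMP arrays, rose by 7.09 ± 0.34. Monocyte and dendritic cell markers went both ways, with 6 of 15 higher and 7 lower (6 and 7 adjusted over the list alone). Their median was -0.13 although camera put the list upward (adjusted p = 0.883), and it turned to 0.58, 0.17 and 0.22 with quantile normalization, the percentile over detected probes and spike-in scaling. All 8 hemoglobin genes were higher (8 adjusted over the list alone; camera adjusted p = 1.96e-06, and adjusted p = 0.0302 with an estimated correlation). Hbb-bs rose by 6.28 ± 0.27 to a level of 4.78, against 10.50 in early erythroblasts. Erythroid membrane genes were higher for 21 of 26 and lower for 1 (21 and 1 adjusted over the list alone; camera adjusted p = 9.93e-08, and adjusted p = 0.226 with an estimated correlation). Heme and iron genes were higher for 5 of 24 and lower for 17 (5 and 17 adjusted over the list alone; camera adjusted p = 0.306). Antigen presentation and interferon genes were higher for 20 of 27 and lower for 3 (20 and 3 adjusted over the list alone; camera adjusted p = 4.78e-07, and adjusted p = 0.0587 with an estimated correlation). Eosinophil, basophil and mast cell markers were higher for 13 of 18 and lower for 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.000756, and adjusted p = 0.226 with an estimated correlation). Platelet genes were higher for 17 of 26 and lower for 2 (18 and 2 adjusted over the list alone; camera adjusted p = 5.43e-05, and adjusted p = 0.158 with an estimated correlation).

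**Figure D4:**
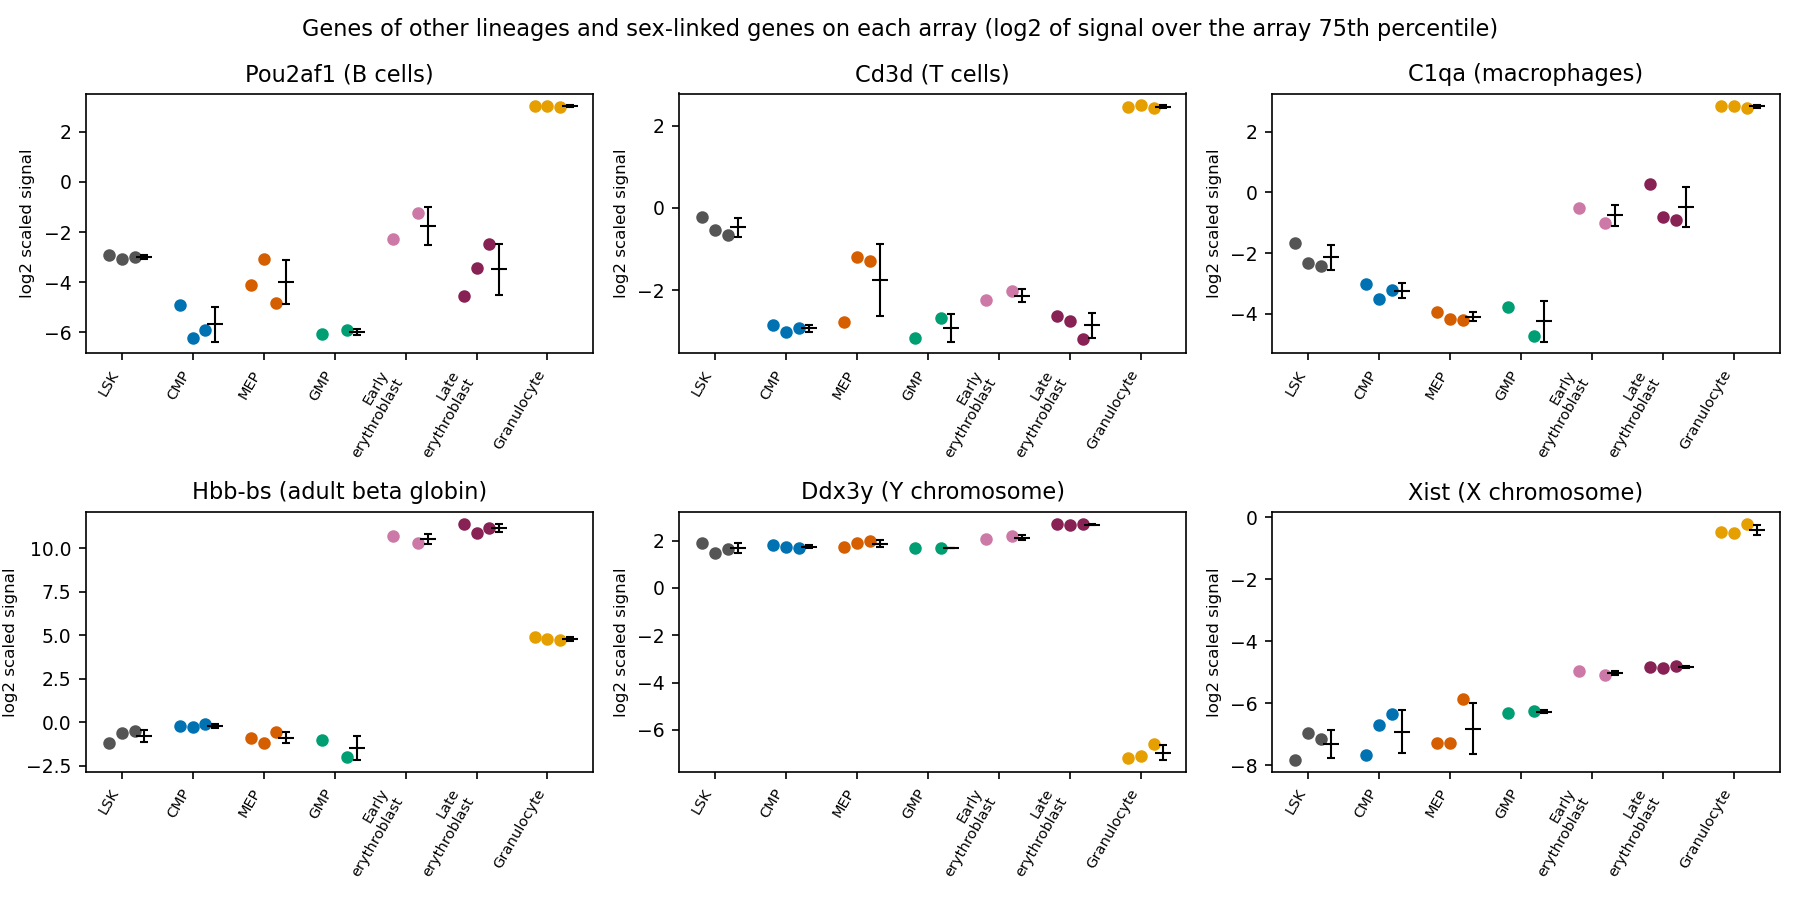
Levels of Pou2af1, Cd3d, C1qa, Hbb-bs, Ddx3y and Xist per array (log2 signal relative to the 75th percentile of the array), 1 point per array with the mean and SD of each cell type. Ddx3y is well above background on 0 of 3 granulocyte arrays and 16 of 16 others, the drawn feature of Xist on 3 of 3 and 0 of 16, and Hbb-bs averages 4.78 in granulocytes and 10.50 in early erythroblasts.

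Endothelial and stromal markers were higher in granulocytes than in GMP for 5 of 10 and lower for 3 (5 and 3 adjusted over the list alone; camera adjusted p = 0.157). The 3 granulocyte arrays were also the only ones without signal of the Y-linked gene Ddx3y, well above background on 0 of them and on 16 of 16 others. Of Xist, the noncoding RNA of the inactive X chromosome, 1 feature was well above background on 3 of 3 granulocyte arrays and 0 of 16 others. A second feature, which the files name XIST, was so on 3 of 3 and on 2 of 16, both early erythroblast arrays (levels -0.12 and -0.86, against a mean of 2.11 in granulocytes). The labels do not give the sex of the mice. In all, 15291 of 22951 features differed, 6360 higher and 8931 lower in granulocytes. The share higher was 41.6%, against 52.7% with the percentile over detected probes and 64.3% of 6739 calls with spike-in scaling, where the medians of all features were -0.19, 0.12 and 0.16. No slide held both cell types, so no value within a slide could be had. Slide 5 held only granulocyte replicates 2 and 3. With the slide as a fixed block the granulocyte level thus rests on replicate 1 alone, and its count is not given.

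Many genes changed differently on the erythroid path from MEP to late erythroblasts and on the granulocytic path from GMP to granulocytes. Of 15099 features well above background on every array of all 4 cell types, 11803 (78.2%) differed between the paths, 6430 more positive on the erythroid and 5373 on the granulocytic path. The count was 17806 when 1 of the 4 cell types sufficed. With the slide as a fixed block the granulocyte level rests on replicate 1 alone, and that count is not given. The share more positive on the erythroid path was 54.5%, against 0.6% of 14002 calls with spike-in scaling, where the median of all features moved from 0.23 to -4.55. Ube2o, a ubiquitin-conjugating enzyme of reticulocytes, changed by 7.67 on the erythroid and -0.59 on the granulocytic path, a difference of 8.26 ± 0.18 (adjusted p = 4.32e-14). The immediate early gene Egr1 changed by -6.43 and 5.08 (difference -11.51 ± 0.97, adjusted p = 3.58e-08), and Pf4 by -7.47 and 1.55 (difference -9.02 ± 0.49, adjusted p = 2.66e-10). The granulocytic change of Pf4 was not called with the slide as a block or without GMP replicate 2. Alas2 rose on both paths, by 12.99 and 5.69. The granulocyte arrays also carried genes of red cells, platelets and other lineages, lacked Ddx3y signal and shared no slide with GMP. The granulocytic change may therefore not be of maturation alone. For Ltf (4.25 and 4.46) and Cebpa (-2.70 and -2.12) the difference did not pass the test, with adjusted p = 0.747 and 0.502. With spike-in scaling the changes stood apart, at -0.18 and 4.81 for Ltf and -7.12 and -1.77 for Cebpa.

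Both paths fell for 4364 features (2783 from independent lists) and both rose for 2385 (1629), while 1242 rose on the erythroid and fell on the granulocytic path (2766) and 926 did the reverse (1639). With spike-in scaling these counts became 788 (741), 78 (20.8), 2 (10.4) and 1357 (1484). Across features, which are not independent replicates, the changes correlated with r = 0.404 and rho = 0.458. Ribosome biogenesis genes fell on both paths for 30 of 31 and oxidative phosphorylation genes for 29 of 36. Of 24 heme and iron genes, 14 rose on the erythroid and fell on the granulocytic path, and for 22 the erythroid change was the higher. Cell cycle genes had the higher change on the erythroid path for 37 of 41, and platelet genes the lower for 14 of 16. Of 31 secondary and tertiary granule genes, 23 rose on both. With spike-in scaling the median difference between the paths turned from 1.96 to -2.82 for cell cycle genes and moved from 4.83 to 0.05 for heme and iron genes. The median erythroid change then turned from 3.76 to -0.67 for heme and iron genes and from 2.84 to -1.58 for the granule genes.

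**Figure D5:**
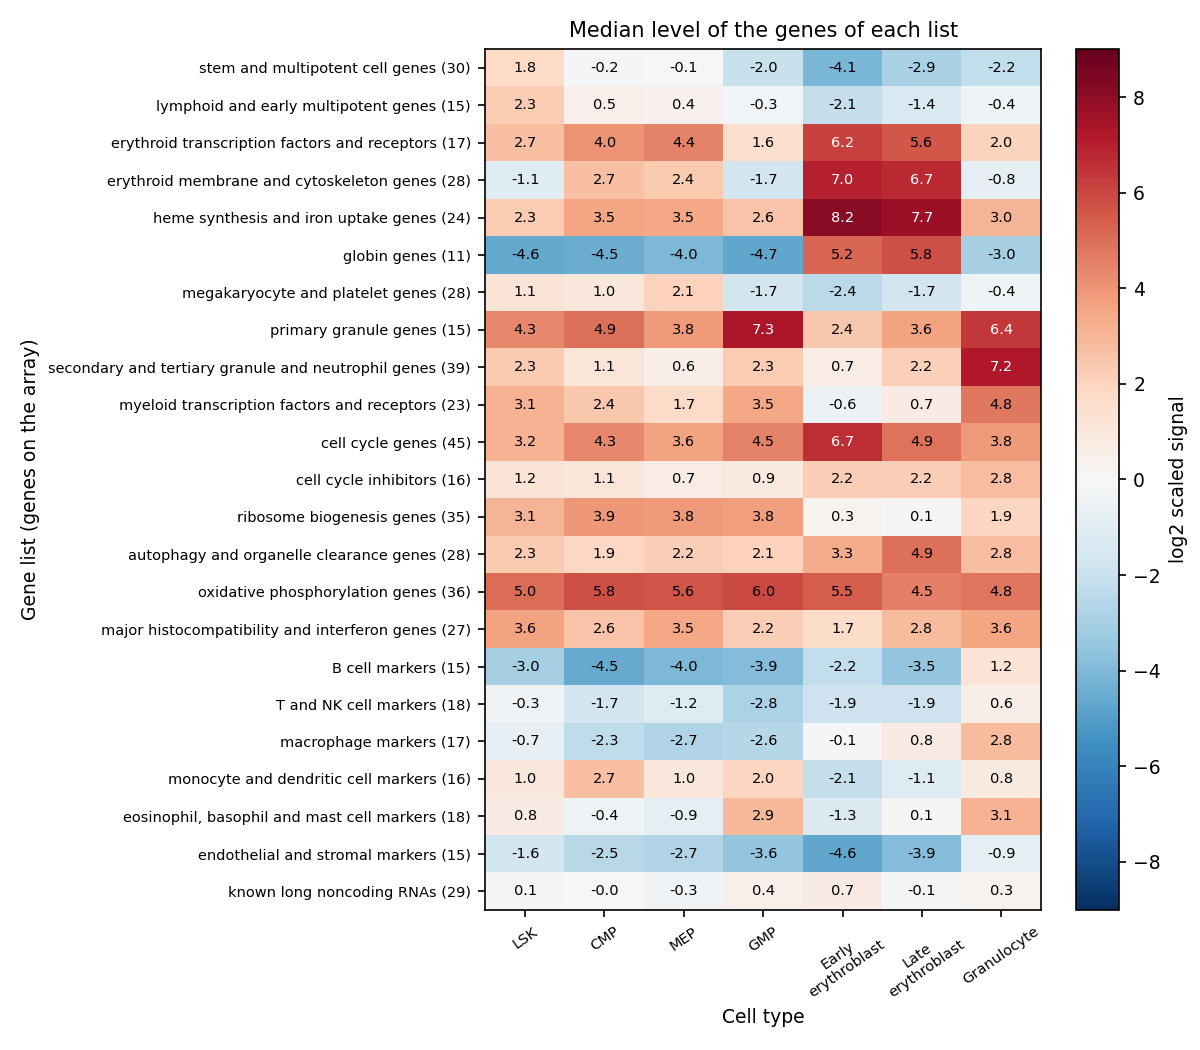
Median level of 23 gene lists in each cell type (log2 signal relative to the 75th percentile of the array, mean of the arrays per gene), with 1 cell per list and cell type and the value printed in it. Ribosome biogenesis genes fall from 3.83 in MEP to 0.29 in early erythroblasts and erythroid membrane genes rise from 2.37 to 6.99, while the rise of cell cycle genes from 3.60 to 6.66 turns under spike-in scaling.

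Almost every feature varied across the 7 cell types, and the custom noncoding features did so in a smaller share than named genes of like signal, an order that 2 alternatives turned. By limma's F test 23874 of 26224 features (91.0%) varied, and of the named genes 14136 of 15030 (94.1%). Of 1056 custom features tested, 907 (85.9%) varied, against 89.9% of named genes matched on signal (95% of 10000 draws between 88.2% and 91.6%, adjusted p = 6e-04). The difference of -4.02 percentage points turned to 0.48 with the mean of all probes (adjusted p = 0.912) and to 2.23 after normexp background correction (adjusted p = 0.0844). The share was 94.3% of set 1 against 95.7% of matched genes (adjusted p = 0.577), 85.7% against 86.9% of set 2 (0.954), 85.4% against 90.3% of set 3 (0.0045) and 84.0% against 88.4% of set 4 (0.0024). Intergenic noncoding regions of the catalogue varied for 83.8%, against 89.4% (adjusted p = 6e-04), and this too reversed with both alternatives.

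Some custom features differed strongly between lineages. TCONS_00312140 rose by 4.83 ± 0.21 from LSK to CMP, fell by 5.71 ± 0.23 from CMP to GMP and was higher in MEP than in GMP by 5.30 ± 0.23. TCONS_00060256 was higher in MEP than in GMP by 6.30 ± 0.57 and fell by 4.28 ± 0.57 in early erythroblasts. TCONS_00236091 and TCONS_00108378 rose by 9.21 ± 0.33 and 8.54 ± 0.18 from MEP to early erythroblasts, TCONS_00152926 by 4.02 ± 0.21 from early to late erythroblasts, and TCONS_00375085 by 11.06 ± 0.64 from GMP to granulocytes. For each of these 6 features, all 3 probes moved the same way. From MEP to early erythroblasts 695 of 887 custom features differed, 477 higher and 218 lower. Over all features of that comparison 53.6% of the calls were higher, against 3.2% with spike-in scaling, so the split rests on the scaling. Between MEP and CMP 40 of 879 custom features differed, 20 each way. In the other comparisons 281 of 947 differed between CMP and LSK, 131 of 872 between GMP and CMP, 228 of 836 between MEP and GMP, 364 of 713 between late and early erythroblasts and 508 of 862 between granulocytes and GMP. Positions of these features in the genome were not used here.

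Long noncoding RNAs with names were higher in CMP than in LSK for 10 of 26 and lower for 8 (10 and 8 adjusted over the list alone); their median of 0.32 turned to -0.01 with the percentile over detected probes, and camera put the list downward (adjusted p = 0.883). The imprinted Meg3 was well above background on 0 of 3 CMP arrays and at least 33.9-fold lower than in LSK (adjusted p = 3.5e-07), and the small nucleolar host gene Snhg3 rose by 1.68 ± 0.10. In late erythroblasts Malat1 and Neat1 were higher than in early ones by 1.38 ± 0.15 and 1.22 ± 0.16. Of the 7 genes of the sorting markers, 4 were higher in GMP than in CMP and 0 lower (4 adjusted over the list alone; camera adjusted p = 0.00426, and adjusted p = 0.286 with an estimated correlation), such as Fcgr3, which encodes CD16 (4.12 ± 0.37). As the gates select on these proteins, they check the sort and are no findings.

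Few features were detected in a single cell type. Of 342 that were well above background on every array of 1 cell type and on no other array, 191 belonged to granulocytes, 100 to LSK cells, 26 to late and 20 to early erythroblasts, 3 to GMP and 1 each to CMP and MEP. In LSK cells these included Clip3, Sema3d and Susd4, with Clip3 at least 2.31-fold above the next cell type. Cyp4a32 and Reg3g were found so in early erythroblasts, the autophagy protease gene Atg4a in late erythroblasts, Upk1b in CMP, Megf10 in MEP, and Slc44a4 and Mfap3l in GMP. For Upk1b, Megf10, Slc44a4 and Mfap3l the bound against the next cell type was only 0.57-fold, 0.37-fold, 0.79-fold and 0.68-fold. As these bounds lie under 1, a like or higher level of these genes in another cell type could have gone undetected. Of the custom features, 4 were detected in a single cell type, 3 of them in granulocytes. The detection flag also passed 9.57% to 27.88% of olfactory and vomeronasal receptor genes, depending on the array. As these were taken as silent in blood, passing the flag need not mean expression. Without early erythroblast replicate 1, 583 features were detected in a single cell type, since a cell type with fewer arrays meets the rule more easily. Among the 191 of granulocytes, the named genes Ces1d and Ccr1 stood at least 13.7-fold and 9.52-fold above the next cell type. The largest bound there, 160-fold, was of a feature without a gene name. The granulocyte arrays also carried markers of other lineages and lacked Ddx3y signal, so the 191 need not all be expressed by granulocytes.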

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

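The tests on scaling, on dim features, on the floor, on sex-linked genes and on the spread of the granulocyte arrays were chosen only after the result was seen. That on further lineage markers and the splits of arrays were chosen before.

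The change from progenitor to mature cell differed between the erythroid and granulocytic paths for 11803 features by limma's interaction test. For Pf4 the erythroid change lay below the granulocytic one by a log2 difference of -9.018. With the 3 granulocyte arrays counted as 1 sample, an alternative added after seeing the data, the interaction called 10611 features.

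Markers of B cells, T cells and macrophages were higher on granulocyte than on GMP arrays. Background was argued against, since olfactory and vomeronasal receptor genes, taken as silent in blood, had a median difference of -0.607, opposite to the markers. Yet 10.78% to 18.99% of them were well above background on granulocyte arrays and 9.57% to 10.7% on GMP arrays. By the detection flag the receptor genes were thus not all silent. These genes were dim, with medians of -6.58 in granulocytes and -6.01 in GMP, so they cannot show what scaling does to brighter markers. Under the other scalings the median differences of the fixed lists stayed between 3.08 (T and NK cell markers) and 5.08 (macrophage markers). RNA of B cells, T cells and macrophages in the granulocyte preparation could account for the higher markers. Of further markers outside the fixed lists, 14 of 18 tested for B cells and 10 of 12 for T and NK cells were higher. So were 17 of 18 for macrophages, with 1 lower. The lowest share was 77.8%, against 27.0% of all genes. Markers not well above background on every GMP array, such as Mzb1 and Ms4a7, were tested only through their granulocyte signal. They could only be called higher. The 27.0% was not matched on GMP level, so the gap between the shares may rest in part on the filter. Abundant genes of these cells were among the higher markers, with the plasma cell gene Jchain at 7.83 and the macrophage gene Fcna at 2.72 on the array scale. The gate took Gr1-positive cells, which should remove most other lineages, and expression by the granulocytes themselves stays open, as bulk RNA does not separate cells.

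Dim features were called higher on early erythroblast than on MEP arrays. The low signal of erythroblast arrays may account for the dim ones, as all 1327 olfactory and vomeronasal receptor genes, taken without a filter, had a median log2 difference of 1.91 (quartiles 1.57 and 2.20), against 1.90 for other genes of the same MEP level (95% of draws between 1.89 and 1.91). With every value raised to the highest floor of any array, 7330 of 8457 features higher by 2-fold or more stayed so, or 86.7%. For these 7330 the floor was argued against as the whole cause. The 8457 were taken at any MEP level, and the rule for calls already asked for detection on every early erythroblast array. The share is thus not one of bright features alone and rests in part on that rule. Raising the values keeps the scaling on the 75th percentile, which stays open, since with spike-in scaling 609 features were higher and 18296 lower. A true rise of single dim genes stays open.

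The granulocyte arrays stood apart in sex-linked genes and in spread. Ddx3y, Eif2s3y and Uty, well above background on 0, 1 and 0 of 3 granulocyte arrays, were lower there than in every other cell type, by at least 83.6-fold, 177-fold and 1.94-fold (a log2 bound of 0.959 for Uty). Both features of Xist were higher on each granulocyte array than on all 16 others, where 1 was well above background on 0 and the other on 2, both of early erythroblasts; this is consistent with RNA from female mice on these arrays and male mice on the others. A difference of sex then goes with every comparison of granulocytes, and its share in them was not tested. The pairs of granulocyte arrays had an SD between 0.083 and 0.107, against 0.153 to 0.341 elsewhere. The ratio of this SD to that between spots of 1 probe was 1.605, against 3.135 to 4.293 in the cell types other than MEP. The MEP ratio of 1.875 went with a spot SD of up to 0.2026, against 0.057 to 0.062 on granulocyte arrays. The pair SD of MEP arrays was 0.153 to 0.264. The granulocyte ratio leaves open whether 1 RNA was hybridised 3 times.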

How the results depend on the processing

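The common floor, spike-in scaling, the looser filter and both treatments of the granulocyte arrays were chosen only after the result was seen. Over the alternatives chosen beforehand, a value was counted as the same if it kept its direction and call, or for counts its size within 1.5 times. A change of sign also counted as the same where the main result had not passed the test. Custom set 1, for example, went from -1.42 to 1.46 percentage points with quantile normalization. The same were 198 of 222 values for 17 counts and shares, and 555 of 672 for gene lists, with 110 weaker and 7 stronger. For named genes 8585 of 9079 were the same, with 458 weaker, 33 stronger and 3 reversed. The 1032 features of MEP against CMP became 2002 with normexp, 644 with no filter, 0 with only the groups compared (limma, 4268 of 22842 unadjusted), 1727 with the common floor, 24 with spike-in scaling and 613 without granulocyte arrays. Without 1 array the count lay between 302 and 1233, at 302 without CMP 2, 325 without CMP 3, 525 without MEP 2 and 492 without MEP 3. Spike-in scaling gave 1747 for CMP against LSK, 1677 for GMP against CMP, 2966 for MEP against GMP and 6739 for granulocytes against GMP. The log2 spike-in offsets varied between arrays of 1 cell type, with an SD from 0.11 in GMP to 0.61 in LSK cells. The cause of the lower counts was not tested. With no filter, which tests more features, early erythroblasts against MEP gave 29170 and the interaction 26982, and the stricter filter, which tests fewer, gave 14466 for the F test. For the interaction the stricter filter is the one used throughout, and detection in 1 of its 4 groups, which tests more, gave 17806. Features of 1 cell type numbered 562 when most arrays sufficed, 622 when 1 other array was allowed, and 350 to 583 without 1 array, with 583 without early erythroblast replicate 1. Of 109 list calls, 10 held with an estimated correlation.

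The shortfall of custom features reversed to 0.48 with the mean of all probes and 2.23 with normexp, that of set 3 to 0.45 and of set 4 to 3.48 with normexp, and that of intergenic regions to 0.12 and 5.06; the cause was not tested. Set 2 reached -12.2 with quantile normalization but turned to 1.79 with no filter, 5.98 with the mean of all probes and 0.56 with normexp. Set 3 stood at -0.44 and set 4 at -0.23 with the mean of all probes, and set 3 at -2.08 with no filter. With normexp Fcrla turned from -1.30 to 0.14 in GMP against CMP, Stab2 from 2.12 to -0.12 in MEP against GMP and Ms4a2 from -2.15 to 0.68 in early erythroblasts against MEP; the cause was not tested.

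Replicate numbers were not taken as pairs, since not every pair of same-numbered arrays correlated above 0.1. The values were -0.46, -0.24 and -0.52 for CMP against LSK, 0.24, -0.02 and 0.41 for MEP against CMP, whose same-numbered arrays shared slides 2, 3 and 4, and between -0.14 and 0.48 in the other comparisons. With the replicate block limma called 8616 for CMP against LSK, 845 for MEP against CMP, 3787 for GMP against CMP, 6595 for MEP against GMP, 18425 for early erythroblasts, 11200 for late ones, 15060 for granulocytes, 11701 for the interaction and 23760 by the F test. Of the 10 splits of 6 arrays, 1 called as many features as the real one, itself, for CMP against LSK (8893, highest other 245), and 1 for MEP against CMP (1032, highest other 2); 10 splits are too few for a share under 0.05. The low signal over background of erythroblast arrays limits what can be said of dim features there.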

Other observations

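The tests of other lineages' further markers were chosen before the result was seen, and the genes named here from them after.

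Plasma cell and macrophage genes had large differences between granulocyte and GMP arrays beyond the fixed lists. Jchain, which joins polymeric immunoglobulins, rose by 11.19 ± 0.75 (limma adjusted p = 1.02e-08; well above background on 1 of 2 GMP arrays), and Mzb1, an endoplasmic reticulum protein of B lineage cells, was at least 158-fold higher (adjusted p = 8.71e-12). Fcna, a macrophage ficolin, also above background on 1 of 2 GMP arrays, rose by 6.41 ± 0.37 and Slc11a1, a metal transporter of phagosomes, by 5.54 ± 0.30. Ms4a7 was at least 77.0-fold higher (adjusted p = 1.25e-09). The T cell costimulator gene Icos was at least 7.80-fold higher (adjusted p = 9.28e-10), while Klrk1 (0.38, adjusted p = 0.659) and Prf1 (-0.23, adjusted p = 0.433) did not pass the test, and the macrophage gene Trem2 was lower by a log2 difference of -1.06 (adjusted p = 0.018).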
